A study of Mus musculus with 2 samples.

How the data were processed

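ATAC-seq was performed on forebrain tissue of mouse embryos at embryonic day 13.5, with tagmentation by the Nextera transposase, per the labels. The labels give 1 group and number its 2 samples as biological replicates 1 and 2, each from pooled embryos of both sexes, and both samples entered every comparison. The deposited data used here were peak lists on the mm10 assembly, derived from filtered alignments per the submitters' accompanying notes. The aligner, the peak caller, their versions, any shift of reads for the transposase and the blacklist, if any, were not given in the sources used here. Peaks were listed for each replicate on its own and for the series, each as a ranked list, a list thresholded on the irreproducible discovery rate (IDR, the expected share of peaks whose ranks do not repeat) and a pseudoreplicated list. The series also had a conservative thresholded list and a replicated list. From the values, the conservative list follows the ranking of true replicates, and the other thresholded series list that of pooled pseudoreplicates.

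Each peak carried the authors' enrichment value, −log10 p-value and −log10 q-value, in the narrowPeak format named in the deposited notes. The enrichment value is called fold enrichment here. That it is a ratio over local background was inferred, since the peak caller was not given. The deposited score was a scaled IDR in thresholded and ranked lists, with 540 for an IDR of 0.05 and 830 for 0.01, and 10 times the −log10 p-value in the other lists, found by recomputing it from the other columns. Summits were given as an offset in bp. All these values are the authors' own and were used only to describe, rank and filter peaks within a list. An interval often held several summits, with a mean of 2.72 per region and more than 1 in 81.8% of regions of the conservative list. In that list 1666 peaks (2.10%) had a q-value above 0.05, since reproducibility and not the q-value set the threshold. Of the conservative peaks, 76949 (96.9%) were also in the other thresholded series list. Replicate 2 had 1.14 times the peaks of replicate 1, and the thresholded series list 1.23 times those of the conservative list.

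Peak lists hold no read counts, so the depth of each library was unknown, and no value could be weighted by it. The 95% intervals on shares of regions are Wilson intervals and cover counting error only. Means and SDs are over the replicates' own thresholded lists. Tests over genes, regions or summits describe these libraries, because genes and regions are not replicates, and neighbouring genes can share a region.

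Overlapping peaks of a list were merged into regions, each with its highest fold enrichment. Regions overlapping by at least 1 bp counted as shared, and 100 shuffles within chromosomes gave the chance level. The genome was GRCm38, the assembly that mm10 names, with the GENCODE release 21 mouse annotation, and no peak ended beyond its chromosome. A region within 1 kb of any annotated transcript start was called promoter, and the others distal, split into exonic, intronic and intergenic. Sharing of promoter and distal regions was compared by an odds ratio and a chi-square test on counts summed over both lists. A Mantel-Haenszel odds ratio was used within deciles of fold enrichment.

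For gene lists, the 21755 protein-coding genes of chromosomes 1 to 19 and X were scored for a promoter region, and each of 22 lists was compared with all other genes by a two-sided Fisher's exact test. Distal regions went to the protein-coding gene with the nearest start within 500 kb. Each gene's log2 ratio of observed to expected regions used a pseudocount of 0.5, and the mean over a list was set against 100000 random gene sets matched on 10 bins of territory length in a two-sided permutation test. The lists covered pallial, subpallial, diencephalic, radial glia, Notch, neuron, Cajal-Retzius, choroid plexus, midbrain and hindbrain, Hox, astrocyte, oligodendrocyte, microglia, endothelial, pericyte, erythroid, liver, muscle, pluripotency, cell cycle, housekeeping and olfactory receptor genes. Of 473 written entries 472 matched the annotation, Ahsp being the exception, and 12 symbols stood in more than 1 list. For 24 consensus sequences, windows of 75 bp to each side of a summit were scanned on both strands and compared with flanking windows centred 500 bp away by a two-sided exact binomial test on discordant pairs, with 1 flank drawn per summit for the test and the mean of both for the fold. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05.

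Genes were named by a fixed rule. It took the 3 members with the largest excess of distal regions in each list that passed a test, up to 3 members with a promoter region in lists of other tissues, and up to 3 without in forebrain lists. It also took the 20 genes with the highest distal ratio among those with at least 10 distal regions, and the 10 distal regions of highest fold enrichment found in both replicates. Some of the genes it takes in lists near or below expectation are left out of the text for length. Further examples of list members, and genes completing counts of 5 or fewer, were chosen after their values were seen. These are Wnt8b, Nkx6-2, Ank1, Fcgr3 as a promoter example, Hand2, Apoa1, Apob, Ttr, Flt4, Esam, Sox17, Sox2, Sox9, Vim, Tubb3, Dcx, Dlx2, Gsx2, Emx1, Pax6, Foxg1 and Reln, with the neighbouring genes of shared starts.

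The grouping, tests, gene lists, consensus sequences, naming rule and most alternatives were fixed before the data were examined. The alternatives were a stricter IDR of 0.01, other peak lists, other overlap rules, unmerged peaks, promoter distances of 250 and 2500 bp, 1 start per gene, and genes matched on promoter CpG ratio. They also included a territory limit of 100 kb, distal regions over 5 kb, a pseudocount of 2, territories without unsequenced bases, windows of 50 and 100 bp, flanks 1000 bp away, summits matched to flanks in GC within 0.05, and each replicate on its own. Alternatives chosen afterwards were the other replicate's pseudoreplicated list, the conservative list for the promoter share, the strongest summit per region and every alternative for the difference between pallial or subpallial and midbrain or hindbrain factors. Regions were searched by BLAST against the mitochondrial genome (at least 100 bp and 80% identity) and against the assembled chromosomes (at least 95% identity over 50% of the region), the latter with low-complexity masking, which was turned on after a first search of the same 10 regions had given the same counts.

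The distal list test was tested on simulated data with the 21755 genes. The simulations held more distal regions than the data, with noise independent between genes, and used fewer permutations without the olfactory receptor list. Their rates may therefore differ from those of the test on the data. A planted 3-fold excess in the pallial list was called in 19 of 20 simulations, a planted 3-fold deficit in the liver list in 3 of 20, and lists with no planted change in 1 of 380, so the test had little power for lists below expectation. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and BLAST 2.17.0. Chromosome Y was left out of the gene comparisons, and ranked lists were used only for reproducibility values.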

Results

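Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in the forebrain of mouse embryos at embryonic day 13.5. At this stage the pallium, the future cortex, and the subpallium, the future basal ganglia, both contain dividing progenitors and newly born neurons. The labels describe 1 group of 2 biological replicates of pooled male and female tissue from the B6NCrl strain. Replicate 1 had 61395 reproducible peaks, which merged into 23777 regions with a median length of 965 bp and covered 23.2 Mb. Replicate 2 had 70097 peaks in 27787 regions with a median length of 969 bp, covering 27.3 Mb. The conservative list of the series, which compares the 2 replicates, held 79441 peaks in 29159 regions covering 30.8 Mb. Read depth was unknown, because peak lists carry no read counts. The design has no second condition, so the comparisons below are between the replicates, between kinds of region and between groups of genes. Fold enrichment always means the authors' enrichment value for a peak, taken to be a ratio over local background.

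Most accessible regions of the forebrain were found in both replicates, and the strong ones nearly always were. In replicate 1, 82.7% of regions (19657 of 23777, 95% Wilson interval 82.2 to 83.1) overlapped a region of replicate 2, and in replicate 2, 70.7% (19646 of 27787, 70.2 to 71.2) overlapped a region of replicate 1. Shuffled regions overlapped in 2.16% and 1.85% of cases. In the weakest decile of replicate 1, with a median fold enrichment of 4.52, 67% of regions were shared, against 99.6% in the strongest decile at 16. In replicate 2 the corresponding shares were 39.9% at a median of 4.46 and 99.9% at 15.9. The 4120 regions of replicate 1 without a partner in the thresholded list of replicate 2 had a median fold enrichment of 6.29, against 8.61 for its shared regions. The 8141 such regions of replicate 2 had 6.15 against 9.29. Most of both sets were in the other replicate's longer list, as given at the end. With no second group, these shares carry no test across samples.

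**Figure D1:**
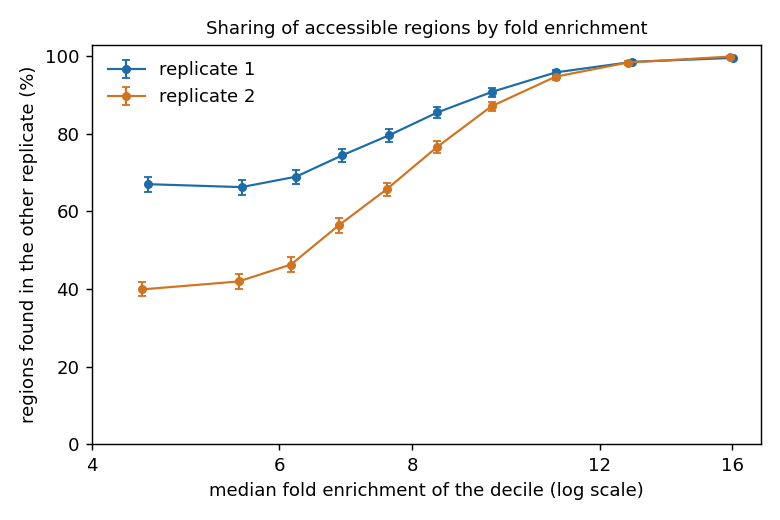
Share of accessible regions of each replicate that overlapped a region of the other replicate (y axis, percent) by decile of fold enrichment, placed at the decile's median (x axis, log scale); bars are 95% Wilson intervals. Sharing reached 99.6% and 99.9% in the strongest deciles and was 67% in the weakest decile of replicate 1 and 39.9% in that of replicate 2.

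Regions at gene starts were shared between the replicates far more often than regions elsewhere. Of 12768 promoter regions in replicate 1, lying within 1 kb of an annotated transcript start, 95.8% were also in replicate 2, against 67.5% of 11009 distal regions. In replicate 2, 87.7% of 13923 promoter regions and 53.6% of 13864 distal regions were also in replicate 1. On counts summed over both lists the odds ratio was 7.32 (95% interval 6.96 to 7.70), and the chi-square test gave a p too small for double precision. Shared regions enter these counts from both lists, so the interval and the test treat dependent counts as independent. Promoter regions were also stronger, and within deciles of fold enrichment the odds ratio fell to 4.67 (4.41 to 4.93), 1 of 6 alternatives tried. At the 19657 paired regions, fold enrichment ranked alike in both replicates, with Spearman's rho of 0.871 and Pearson's r of 0.874 on log2 values. These are correlations across regions, which are not independent replicates. The median log2 difference of replicate 1 minus replicate 2 was -0.07, with an SD of 0.28.

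In the replicates' own lists and in the conservative list, gene starts held a larger share of the accessible regions than any other class. Promoter regions made up 51.9% ± 2.54 (SD, n = 2) of regions, intergenic regions 23.8% ± 0.911, intronic regions 22.4% ± 1.37 and exonic regions 1.90% ± 0.255. In the conservative list, promoters held 14391 of 29159 regions, or 49.4%, and shuffling its regions within chromosomes left 9.07% at promoters, 38.4% in introns and 49.5% between genes. Promoter regions were wider, with a median of 1230 bp against 834 bp in introns and 873 bp between genes. Their median fold enrichment was 9.56 (quartiles 6.65 and 12.96), against 6.33 in introns and 6.73 between genes. The order changed in the series' longer list of replicated peaks, where promoters held 27.7% of 74929 regions, introns 36.6% and intergenic regions 32.5%.

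Of 21755 protein-coding genes on chromosomes 1 to 19 and X, 12923 (59.4%) had an accessible region at a transcript start, and the replicates' own lists gave 56.6% ± 1.97 (SD, n = 2). Radial glia, neuron, Notch, subpallial and pallial genes were above that level. Diencephalic genes, also of the forebrain, were below it, but did not pass Fisher's exact test (adjusted p = 0.0502). All 24 radial glia and progenitor genes had a promoter region, among them Sox2 and Sox9, transcription factors of neural stem cells, at fold enrichments of 8.13 and 8.69, and Vim, an intermediate filament of radial glia, at 8.71. Postmitotic neuron genes had one at 27 of 29 members (93.1%), including Tubb3, neuronal tubulin, at 8.55, and Dcx, a microtubule protein of migrating neurons, at 6.47. Notch pathway genes had one at 20 of 21 (95.2%), with Heyl the exception. Subpallial and GABAergic factors had one at 22 of 26 (84.6%), such as Dlx2 at 5.79 and Gsx2 at 4.86, homeobox genes of the ganglionic eminences, and pallial factors at 20 of 24 (83.3%), such as Emx1 at 6.86, Pax6 at 7.76 and Foxg1, a master regulator of telencephalic fate, at 9.44.

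By Fisher's exact test against all other protein-coding genes, with adjustment over 22 lists, 7 lists were higher. The forebrain lists among them were radial glia genes (exact adjusted p = 2.84e-05, no finite odds ratio), postmitotic neuron genes (odds ratio 9.24, exact adjusted p = 0.000225), Notch genes (13.7, exact adjusted p = 0.00102), subpallial factors (3.76, exact adjusted p = 0.0145) and pallial factors (3.42, exact adjusted p = 0.0299). In the replicates' own lists the shares were 95.8% ± 5.89 for radial glia, 89.7% ± 0 for neuron, 78.6% ± 3.37 for Notch, 76.9% ± 0 for subpallial and 77.1% ± 14.7 for pallial genes (SD, n = 2), each above the share of all genes in both replicates. The cell cycle list, with 23 of 23 members (exact adjusted p = 4.48e-05), and the housekeeping list, with 25 of 25 (exact adjusted p = 2.54e-05), were higher as well. Some of the best known forebrain factors had no promoter region in the conservative list. They were Tbr1, of postmitotic pallial neurons, Eomes, of intermediate progenitors, Neurod4 and Wnt8b among pallial genes, and Nkx2-1, of the medial ganglionic eminence, Lhx6, Lhx8 and Nkx6-2 among subpallial genes. Eomes had one in replicate 2 alone, at a fold enrichment of 4.31, and Lhx8 had one in both replicates' own lists, at 3.93 and 6.86. Nhlh2 and Rbfox3, which encodes the neuronal marker NeuN, were the neuron genes without one. Most of these absences, and that of Heyl, were limited to the thresholded list. In the longer replicated list, 23 of 24 pallial, 26 of 26 subpallial, 29 of 29 neuron and 21 of 21 Notch genes had a promoter region. The share of other genes there was 66.5%.

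Hox genes, which pattern the hindbrain and spinal cord, had a promoter region at 2 of 39 members (5.13%, odds ratio 0.0368, exact adjusted p = 9.35e-12). These were Hoxd1 on chromosome 2 (74762602 to 74763435, fold enrichment 5.38) and Hoxa1 on chromosome 6 (52157824 to 52159053, 5.15), and neither replicate's own list held a promoter region at any Hox gene. In the replicated list, 14 of 39 had one (35.9%, odds ratio 0.281, exact adjusted p = 0.000415). Diencephalic and hypothalamic factors had one at 9 of 24 members (37.5%, odds ratio 0.410, exact adjusted p = 0.0502), Barhl2, Foxb1 and Gata2 being among those without, and midbrain and hindbrain genes at 10 of 24 (41.7%, odds ratio 0.488, exact adjusted p = 0.111). Neither passed the threshold in the conservative list. Both were lower when promoters were taken within 250 bp (29.2%, exact adjusted p = 0.00985, and 33.3%, exact adjusted p = 0.0302) and without replicate 2 (29.2%, exact adjusted p = 0.0186, and 25%, exact adjusted p = 0.00581), while in the replicated list both stood at 79.2%. Within the midbrain and hindbrain list, Pax5 had the strongest region (chromosome 4, 44703786 to 44704929), at 16.3 ± 0.192 over the replicates (SD, n = 2), followed by Mafb at 9.03 ± 0.149 and Gata3 at 8.95 ± 2.62. Cajal-Retzius genes, of the earliest cortical neurons, had a promoter region at 10 of 16 members (62.5%, exact adjusted p = 1), with Reln, the secreted protein that guides cortical layering, at a fold enrichment of 6.80. Choroid plexus and dorsal midline genes had one at 10 of 18 (55.6%, exact adjusted p = 0.851), with Ttr, the choroid plexus thyroxine carrier, at 7.01. The choroid plexus list fell to 4 of 18 (22.2%) without replicate 2 (exact adjusted p = 0.0114) and at the stricter reproducibility threshold (exact adjusted p = 0.0118).

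Genes of other tissues mostly lacked promoter regions. By the same exact test, shares were lower for microglia and macrophage genes (4 of 20, odds ratio 0.171, adjusted p = 0.00102), endothelial genes (6 of 20, 0.293, adjusted p = 0.0167), erythroid genes (4 of 19, 0.182, adjusted p = 0.00164), liver genes (6 of 22, 0.256, adjusted p = 0.00661), muscle genes (4 of 24, 0.136, adjusted p = 8.12e-05) and pluripotency and germ cell genes (2 of 20, 0.0758, adjusted p = 2.84e-05). Olfactory and vomeronasal receptors, expressed in sensory neurons of the nose, had a promoter region at 3 of 1466 genes (0.205%), with an exact p too small for double precision. The endothelial call ended in the other thresholded series list (8 of 20, exact adjusted p = 0.0947) and in the replicated list (11 of 20, exact adjusted p = 0.377). In the replicated list the shares also rose to 30% for microglia, 40.9% for liver, 41.7% for muscle and 25% for pluripotency genes and to 0.614% for olfactory receptors, and these calls held. Leaving out 1 replicate used the other's own shorter list, with promoter regions at 55.2% (replicate 1) or 58.0% (replicate 2) of all genes. With these lists several shares moved the other way. Without replicate 2 they were 2 of 20 for endothelial, 2 of 19 for erythroid, 4 of 22 for liver, 2 of 24 for muscle and 1 of 20 for pluripotency genes, and without replicate 1 microglia genes had 1 of 20. Olfactory receptors instead rose to 5 of 1466 without replicate 2. Astrocyte genes (8 of 16, exact adjusted p = 0.501), oligodendrocyte genes (6 of 16, exact adjusted p = 0.104) and pericyte, mesenchyme and meningeal genes (9 of 22, exact adjusted p = 0.104) did not pass, at odds ratios of 0.683, 0.410 and 0.473. Without replicate 2, the oligodendrocyte (25%, exact adjusted p = 0.0291) and pericyte lists (31.8%, exact adjusted p = 0.0389) did pass as lower, the latter also at the stricter threshold (27.3%, exact adjusted p = 0.0239).

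Some of the exceptions lay only at starts shared with a neighbouring gene. They were 3 of 6 liver genes, 1 of 4 muscle genes, 1 of 6 endothelial genes and 1 of 3 receptors. No erythroid, microglial or pluripotency gene with a promoter region did so. In the liver list, Vtn shared its region with Sarm1 (chromosome 11, 78496959 to 78498438, fold enrichment 13.2), Foxa3 with Sympk (12.9) and Apoh with Prkca (11.6), and the rest were Apoa1, Apob and Ttr, the last also in the choroid plexus list. Among muscle genes, Myl4 shared a region with Cdc27 (13.2), while Myh7 (6.34), Myf6 (5.51) and Hand2 (4.13) did not. Vmn1r4 shared one with Nt5c3 (11.8), unlike the odorant receptors Olfr94 (8.36) and Olfr452 (8.21). Egfl7 shared one with the gene model Gm20532 (5.93), unlike Erg (8.50), Kdr, the main VEGF receptor (6.5), Flt4 (5.76), Esam (5.20) and Sox17 (4.18) in the endothelial list. Over all protein-coding genes, 2607 of the 12923 with a promoter region (20.2%) had only regions that they shared in this way. Sharing was thus common among all genes, and no test was made of whether it was more frequent among the exceptions. Unshared regions stood at Klf1 (7.86), Gypa (7.59), Epor (5.42) and Ank1 (4.95) among erythroid genes, at Fcgr3 (4.54), C1qc (6.22), Hexb (5.28) and Tmem119 (5.07) among microglial genes, and at the germ cell gene Dazl (9.99) and Esrrb (6.83). The members of the glial and mural lists with the highest promoter fold enrichment, 7 of these 9 below the median promoter region at 9.56, were Mlc1 (11.2), Ntsr2 (8.92) and Aldh1l1 (7.07) for astrocytes, Ugt8a (10.1), Pdgfra (8.62) and Ermn (7.46) for oligodendrocytes, and Kcnj8 (9.38), Fbln1 (8.27) and Tbx18 (8.06) for the pericyte and mesenchyme list. Of the genes in this paragraph, Tmem119, Hand2 and Sox17 had no promoter region in either replicate's own list. C1qc, Hexb and Olfr94 had one in replicate 1 alone, and Apob, Ttr, Egfl7, Erg, Flt4, Epor, Gypa, Myf6, Ermn and Esrrb in replicate 2 alone.

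**Figure D2:**
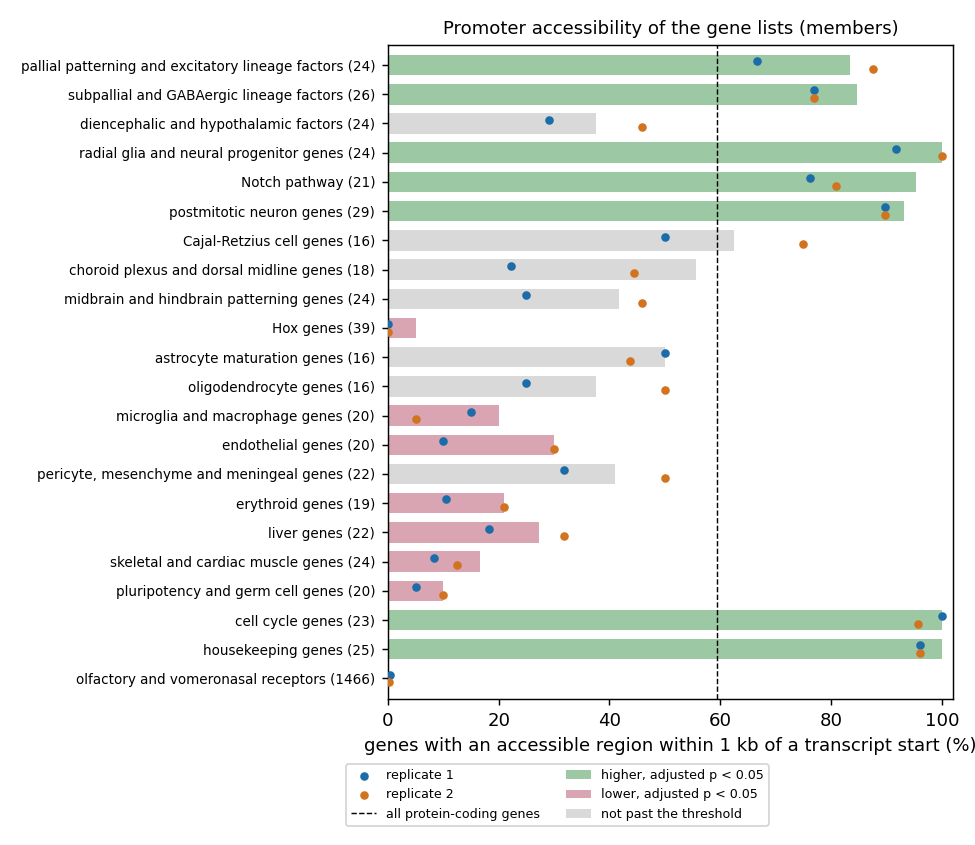
Percent of genes in each list with an accessible region within 1 kb of a transcript start (x axis) for the 22 lists (y axis, number of members in brackets); bars are the series' conservative list, points the replicates' own lists, and the dashed line all protein-coding genes at 59.4%. Bars for radial glia, cell cycle and housekeeping genes reach 100%, and those of Hox genes and olfactory receptors end at 5.13% and 0.205%.

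Promoters differ in CpG content, and matching on it moved several calls. A permutation test against genes of the same decile of promoter CpG ratio kept postmitotic neuron genes above expectation (93.1% against 69.4%, permutation adjusted p = 0.00088), as well as radial glia genes (100% against 81.4%, permutation adjusted p = 0.00691) and housekeeping genes (100% against 83.7%, permutation adjusted p = 0.0116). Hox genes (5.13% against 80.7%), pluripotency genes (10% against 57.2%) and olfactory receptors (0.205% against 9.52%) stayed below it. Diencephalic factors (37.5% against 83.6%) and midbrain and hindbrain genes (41.7% against 85.1%) now fell below it as well. Each of these lists had a permutation adjusted p of 8.8e-05, from the smallest unadjusted p that the permutations can give. The calls ended for subpallial factors (84.6% against 83.3%, permutation adjusted p = 1), pallial factors (83.3% against 68.8%, permutation adjusted p = 0.123), Notch genes (95.2% against 81.0%, permutation adjusted p = 0.105) and cell cycle genes (100% against 89.9%, permutation adjusted p = 0.195). They also ended for microglia (20% against 27.6%, permutation adjusted p = 0.697), endothelial (30% against 50.9%, 0.0616), erythroid (21.1% against 24.7%, 1), liver (27.3% against 26.9%, 1) and muscle genes (16.7% against 35.9%, 0.0526). With a stricter reproducibility threshold or with 1 start per gene, the pallial, subpallial and Notch calls ended too, and with promoters within 250 bp the pallial (75%, exact adjusted p = 0.168) and subpallial calls (76.9%, exact adjusted p = 0.0928). The pallial call also ended without replicate 2, the subpallial call without replicate 1, and the Notch call on leaving out either.

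Distal accessible regions were denser than expected around radial glia, subpallial, pallial, neuron and Notch genes, but not by this test around the diencephalic, Cajal-Retzius and choroid plexus lists. Each of 14215 distal regions was given to the protein-coding gene with the nearest start, and a gene's count was set against that expected from the length of its territory at 6.52 regions per Mb. Radial glia genes had 127 distal regions at 24 genes and a mean log2 ratio of 0.87, against -0.40 in random gene sets with territories of matched length. Subpallial factors had 82 regions and a ratio of 0.73 (random mean -0.36), pallial factors 70 regions and 0.61 (-0.35), postmitotic neuron genes 137 regions and 0.46 (-0.44), and Notch genes 35 regions and 0.38 (-0.29). The median member of the Notch list had a ratio of -0.13, lower than the list's mean and below the expectation from territory length, but above the random mean. The medians were 1.13 for radial glia, 0.77 for subpallial, 0.64 for pallial and 0.67 for neuron genes. Over the replicates' own lists the ratios were 0.97 ± 0.32 for radial glia, 0.85 ± 0.10 for pallial, 0.57 ± 0.06 for neuron and 0.35 ± 0.14 for Notch genes (SD, n = 2). Subpallial factors gave 0.03 in replicate 1 and 0.73 in replicate 2.

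The permutation test with adjustment over 22 lists gave adjusted p = 0.00011, the smallest the permutations can give, for radial glia, subpallial and pallial genes, 0.000176 for neuron genes and 0.00631 for Notch genes. Without replicate 2 the subpallial call ended (ratio 0.03, permutation adjusted p = 0.167), and so it did at the stricter threshold (0.08, permutation adjusted p = 0.110). Oligodendrocyte genes, with 14 regions and a ratio of 0.29 (permutation adjusted p = 0.0428), and cell cycle genes, with 19 regions and 0.18 (permutation adjusted p = 0.0494), passed narrowly. Their median members lay at -0.0094 and -0.12, lower than these means and below the expectation from territory length, but above the random means of -0.26 and -0.22. The oligodendrocyte call ended in 3 of 9 alternatives and turned to -0.21 for regions over 5 kb away, and the cell cycle call ended in 6 of 9, with 9 regions and a ratio of -0.063 without replicate 2. Without replicate 2 the Notch list had 23 regions (0.25) and olfactory receptors 31 (-0.32), and without replicate 1 the pallial ratio was 0.93, all with the call kept. Olfactory and vomeronasal receptors had fewer distal regions than matched genes (55 regions, ratio -0.40 against -0.17, permutation adjusted p = 0.00011). In the conservative list, no distal region was given to any of the 39 Hox genes (ratio -0.24 against -0.10, permutation adjusted p = 0.0300), a call that ended in 6 of 9 alternatives. Some of their territories were too short to expect one, such as that of Hoxd9 with 1.41 kb and 0.00922 expected regions. Hoxa1, with 0.423 expected, had 1 distal region in each replicate's own list. The other 13 lists did not pass by the same permutation test in the conservative list. Their ratios and adjusted p were -0.13 and 0.366 for diencephalic, 0.06 and 0.209 for Cajal-Retzius, -0.19 and 0.654 for choroid plexus, -0.03 and 0.266 for midbrain and hindbrain, 0.09 and 0.214 for astrocyte, and -0.13 and 0.654 for microglia genes. They were -0.46 and 0.622 for endothelial, -0.52 and 0.484 for pericyte and mesenchyme, -0.22 and 0.805 for erythroid, -0.21 and 0.964 for liver, -0.37 and 0.517 for muscle, -0.61 and 0.163 for pluripotency, and -0.01 and 0.366 for housekeeping genes. In longer lists some of them passed above expectation. By permutation, Cajal-Retzius genes (0.31, adjusted p = 0.0368) and midbrain and hindbrain genes (0.15, adjusted p = 0.0455) passed in the other thresholded series list. In the replicated list Cajal-Retzius (0.42, permutation adjusted p = 0.0105), midbrain and hindbrain (0.24, permutation adjusted p = 0.0156) and diencephalic genes (0.24, permutation adjusted p = 0.0133) did. Housekeeping genes passed at the stricter threshold (0.17, permutation adjusted p = 0.0424).

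**Figure D3:**
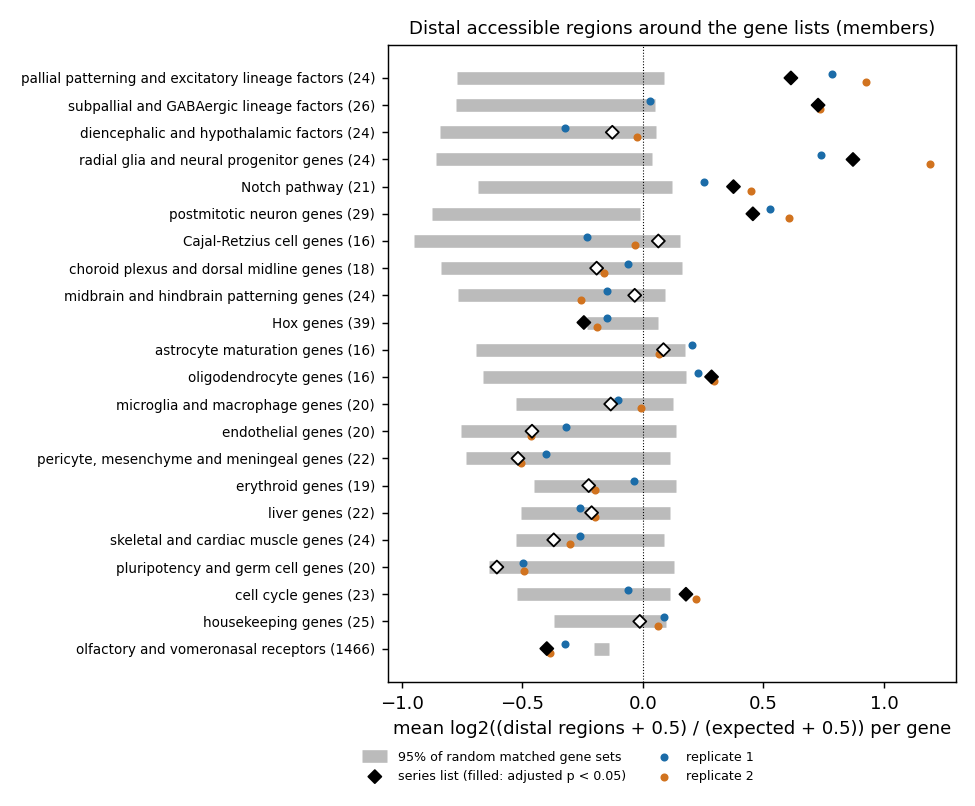
Mean log2 ratio of observed to expected distal accessible regions per gene (x axis, pseudocount 0.5) for the 22 gene lists (y axis, number of members in brackets); diamonds are the series' conservative list, filled where the adjusted p passed, points the replicates' own lists, and grey bars the central 95% of random matched gene sets. Radial glia genes lie farthest right at 0.87, and replicate 1 places subpallial factors at 0.03.

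The genes behind these differences included the main proneural factors. Neurog2, which drives excitatory neurogenesis in the pallium (chromosome 3, 127633135 to 127635631), had 5 distal regions where 0.287 were expected, and Ascl1, its counterpart in the subpallium (chromosome 10, 87490819 to 87493660), had 7 against 0.998. The replicates gave 3.5 ± 0.707 and 7.0 ± 1.41 regions for this pair (SD, n = 2). Other examples from the pallial list were Neurod6 with 6 against 1.2 and Wnt7b with 4 against 0.726. Those from the subpallial list, as written, were Otx1 with 7 against 1.14 and Slc32a1, the vesicular GABA transporter, with 3 against 0.250. Among progenitor and Notch genes, the Notch effector Hes5 had 3 against 0.099, Ptn 10 against 2.06, Sox21 3 against 0.379, Notch1 3 against 0.523 and Nrarp, a feedback inhibitor of Notch, 2 against 0.292. Among neuron genes, the kinesin Kif5c had 8 against 1.19, with 8 in each replicate, the neuronal factor Myt1l 14 against 4.57 and Cux2, of upper-layer neurons, 4 against 1.29. Outside the forebrain lists, single genes also stood above expectation, such as Cspg4, encoding the NG2 proteoglycan of oligodendrocyte precursors, with 3 against 0.263, Aurkb with 3 against 0.0538, Ptprc with 7 against 3.68, Slco1c1, a thyroxine transporter of brain endothelium, with 5 against 1.27, and Olfr1423 with 4 against 0.252.

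Over all protein-coding genes, 15515 had no distal region and 97 had at least 10, with a highest count of 22. Among those with at least 10, Foxo6, a forkhead factor (chromosome 4, 120267079 to 120287349), had the highest ratio, with 10 regions against 0.770 expected (log2 ratio 3.05, replicates 6.0 ± 1.41). Gse1 (chromosome 8, 120228456 to 120581390) had 19 against 2.34 (2.78, replicates 19.5 ± 6.36), and Ncor2, a nuclear receptor corepressor, 10 against 1.28 (2.56). The gene model Gm26897 had 15 against 2.61 (2.32) without a promoter region, and Pja1 on the X chromosome 12 against 2.17 (2.23). The kinases Dclk1 and Dclk2, relatives of doublecortin, had 11 and 10 regions (2.10 and 2.21), Mycn, a growth regulator of neural progenitors (chromosome 12, 12936093 to 12941914), 14 (2.06), and Nfib, a factor of radial glia and glial differentiation (chromosome 4, 82290173 to 82705750), 18 (1.77). The others in the top 20 were Ralgapa2 (2.15), E130114P18Rik (2.15), Bach2 (2.07), Wwc1 (2.04), Ptn (2.04), Dscaml1 (2.00), Msi2 (1.99), Cmpk2 (1.79), Mpped2 (1.78), Noct (1.76) and Maml3, a Notch coactivator (1.72). These genes were ranked by their counts, so no test was made of them. The replicates' own lists could give other counts. They were lower at Mycn (7 and 13), Pja1 (6 and 8) and Msi2 (3 and 6), and on both sides of the series count of 10 at Maml3 (8 and 11).

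None of the 10 strongest distal regions had a gene of the 22 lists as its nearest. The highest fold enrichment, 54.8 in the series and 52.6 ± 0.505 over the replicates (SD, n = 2), lay between genes on chromosome X (143482936 to 143483180), 35.5 kb from the start of Pak3. Next was an intergenic region on chromosome 2 (69355469 to 69355735) at 53.9 and 52.1 ± 0.436, 13 kb from Abcb11, a bile salt exporter of the liver. Of the following 8, intergenic regions on chromosome 5 (60042693 to 60043146, 39.7), chromosome 12 (97061367 to 97061856, 29.7) and chromosome 6 (9889878 to 9890225, 26.7) had no protein-coding gene start within 500 kb. A region on chromosome 10 (96077546 to 96077953, 37.1) lay in an intron of the gene model AC115970.1. The replicates were farthest apart at a region on chromosome 2 (3964421 to 3964690, 36.8), 53.2 kb from Frmd4a, with 29.5 and 40.4. The remaining regions were on chromosome 16 (17222198 to 17222580, 26.5, 11.2 kb from Hic2), on chromosome 17 (70963584 to 70963966, 26.2, in an intron of Gm26561 and 12.2 kb from Myl12b), and on chromosome 17 (17004591 to 17005453, 25.6, 59.1 kb from Zfp960). Matches to mitochondrial DNA of at least 100 bp were present in 5 of these 10 regions.

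Several sequences bound by transcription factors were more frequent at summits than beside them. At 34884 distal summits, the CTCF sequence, bound by the insulator protein CTCF, was present in 3.37% of windows reaching 75 bp to each side against 0.504% of flanking windows in the conservative list. The fold was 7.32 ± 0.0495 over the replicates' own lists (SD, n = 2), the source of all folds in this paragraph unless stated. The E-box CAGCTG, bound by Ascl1 and other bHLH factors, was present at 14.4% of distal summits against 8.18% of flanks in the conservative list, with a fold of 1.90 ± 0.0743 in the replicates, and CAGATG, the E-box form preferred by Neurog2 and Neurod factors, had a fold of 1.49 ± 0.175. Sequences of general promoter factors were above the flanks at distal summits too, with NRF1 at 3.87 ± 1.12, CRE at 2.58 ± 0.149 and the SP/KLF box at 2.11 ± 0.0619, although NRF1 was present at 21 and CRE at 126 of the 34884 summits. Other sequences above the flanks were the POU octamer (1.80 ± 0.0609), the RFX element GTTGCYA (1.77 ± 0.0820), MEIS (1.41 ± 0.0835), SOX (1.32 ± 0.149), the homeobox core TAATTA (1.19 ± 0.0850) and the NFI palindrome (3.27 ± 0.0943). OTX (0.877 ± 0.0565) and RAGGTCA, bound by nuclear receptors including NR2F (0.672 ± 0.153), were below them. The T-box sequence of Eomes and Tbr1 had 0.936 ± 0.0377, but 1.01 in the conservative list, where it did not pass (exact adjusted p = 0.979). At 44557 promoter summits the highest folds were those of ETS at 3.39 ± 0.0461, NRF1 at 3.42 ± 0.209, CRE at 3.28 ± 0.0574 and CTCF at 3.11 ± 0.0685, and the SP/KLF box had 1.89 ± 0.0472. The GATA sequence was rarer at summits than in flanks, at 0.654 ± 0.0234 in distal and 0.501 ± 0.0475 in promoter regions, and TAATTA was rarer at promoter summits (0.451 ± 0.0503). No difference between distal and promoter folds was tested.

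Of 24 sequences, 14 were enriched and 3 depleted at distal summits, and 9 enriched and 10 depleted at promoter summits, by an exact binomial test on the series' conservative list with adjustment over the sequences. Summits of the same region entered as separate pairs, so the p-values treat dependent pairs as independent. Flanks 500 bp away could also lie in the same region, since the list's regions had a median length of 1049 bp. In that list, folds were 6.67 for distal CTCF (exact adjusted p = 3.22e-180), 1.75 for distal CAGCTG (exact adjusted p = 3.1e-150), 1.12 for distal TAATTA (exact adjusted p = 0.000719), 3.22 for the distal NFI palindrome (exact adjusted p = 0.0162) and 3.19 for promoter ETS (exact adjusted p = 4.51e-87). The other distal enrichments were NRF1 (3.23), CRE (2.25), SP/KLF (1.94), the POU octamer (1.68), RFX (1.67), CACGTG (1.54), CAGATG (1.39), MEIS (1.34), SOX (1.28) and TEAD (1.11), and OTX (0.859), the nuclear receptor element RAGGTCA (0.717) and GATA (0.624) the depletions. T-box, AP-1, ETS, the partial REST sequence, MEF2 and FOX did not pass at distal summits, and the HNF1 sequence of liver and kidney factors had no match at any summit or flank of that list. At promoters, CACGTG (1.69), the partial REST sequence (1.85), RFX (1.27) and CAGCTG (1.27) were also enriched, and TAATTA (0.479), GATA (0.546), MEF2 (0.560), OTX (0.624), RAGGTCA (0.635), T-box (0.670), FOX (0.746), CAGATG (0.874), AP-1 (0.874) and TEAD (0.891) depleted. SOX, MEIS, the POU octamer and the NFI palindrome did not pass there.

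Summits were richer in G and C than their flanks, with means of 62.1% and 54.4% at promoters and 50.6% and 45.3% at distal summits. Among summits within 0.05 of their flanks in GC fraction, 5533 distal and 2318 promoter, 8 distal and 2 promoter enrichments were left. The distal enrichments were CTCF (5.55), the POU octamer (1.92), TAATTA (1.74), RFX (1.54), CAGCTG (1.29), SOX (1.29), MEIS (1.22) and CAGATG (1.21), and the promoter enrichments CTCF (6.14) and ETS (2.22). Most sequences that no longer passed also had lower folds in this set. At promoters, NRF1 went from 3.48 to 1.00, CRE from 3.01 to 1.42, SP/KLF from 1.83 to 1.10, CACGTG from 1.69 to 1.03, the partial REST sequence from 1.85 to 1.5 and CAGCTG from 1.27 to 1.13. At distal summits, NRF1 went from 3.23 to 0, NFI from 3.22 to 2, SP/KLF from 1.94 to 1.29, CACGTG from 1.54 to 1.23 and TEAD from 1.11 to 1.01. The exceptions were distal CRE, from 2.25 to 2.62 (exact adjusted p = 0.131), and promoter RFX, from 1.27 to 1.35 (exact adjusted p = 0.196), which were tested on fewer summits. GATA (0.649) and RAGGTCA (0.643) were still depleted at distal summits, where OTX (0.925) no longer was. Of the 10 promoter depletions, 9 ended, and only RAGGTCA (0.559) passed. TAATTA turned to 1.22, AP-1 to 1.40, FOX to 1.29 and CAGATG to 1.00, and GATA was at 0.857, OTX at 0.935, T-box at 0.927, TEAD at 0.872 and MEF2 at 0.5. Taking the strongest summit of each region, chosen after the data were examined, raised distal CTCF to 51.1-fold and promoter ETS to 19-fold.

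**Figure D4:**
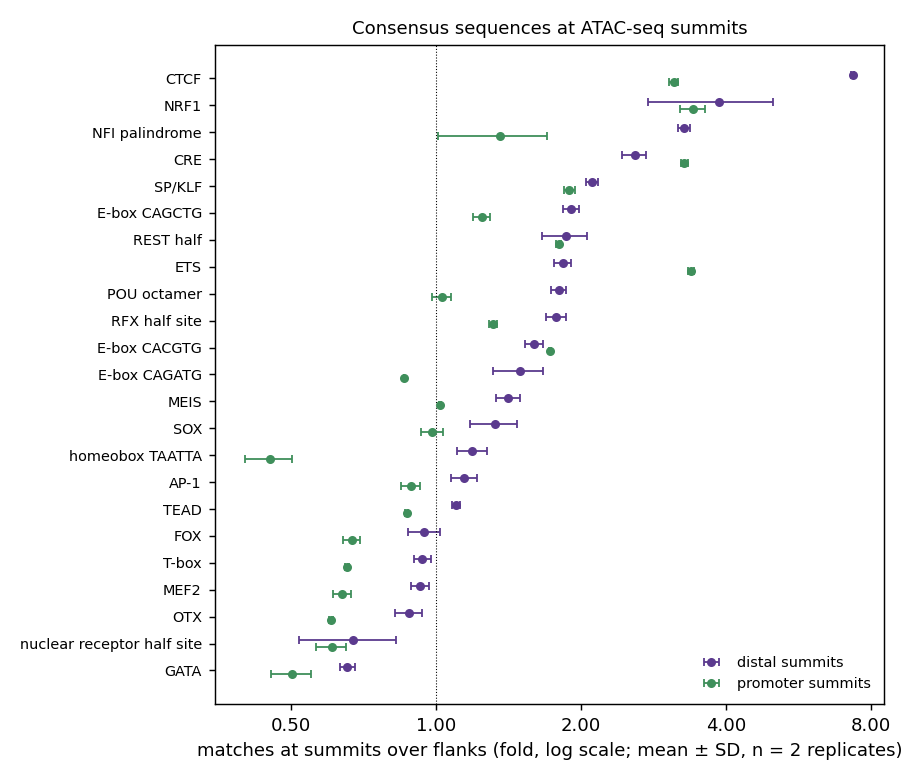
Fold of consensus sequences at summits over flanking windows (x axis, log scale; mean and SD of 2 replicates) for distal and promoter summits (y axis, sequence). CTCF stands highest among distal summits at 7.32, and GATA lies below 1 at both kinds of summit, in windows not matched on GC content.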

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

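Every explanation weighed in this part had its test fixed before the result was seen, while the recomputation under other settings of the difference in the last paragraph and the comparison of weak summits with other summits were tests chosen afterwards. The design has a single group, so no biological explanation was tested for any of the patterns, apart from the comparison of brain regions in the last paragraph.

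Peaks that passed the reproducibility threshold but are absent from the conservative list stood out, because they are a signal outside the peaks analysed above. The ranking of true replicates held 79676 peaks at the threshold, and the conservative list 79441, which leaves 235 in 90 intervals, 74 of the peaks on unplaced scaffolds. The longest interval, on chromosome 1 (24611586 to 24616165), held 15 summits with a −log10 p of 10633.5, at a fold enrichment of 3.56 against a median of 7.19 over the intervals on chromosomes, and matched 4580 bp of mitochondrial DNA at 99.96% identity. High fold enrichment was found on chromosome 9 (24541943 to 24542230, 47.3) and in the gene Chl1 on chromosome 6 (103648978 to 103649357, 41.5). The Chl1 interval had 1 other place in the genome at 95.5% identity, while that on chromosome 9 had neither kind of match. Of 63 intervals on chromosomes, 1 had a mitochondrial match and 15 had another place in the genome. Among 1000 randomly drawn distal regions of the conservative list the counts were 0 and 8. The most other places, 37 and 33, were found for intervals on chromosome 9 (3025442 to 3025775 and 3032294 to 3032737).

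The 10 distal regions of highest fold enrichment, led by those near Pak3 and Abcb11, were searched for sequence found elsewhere. Reads shared with the mitochondrial genome may account for part of them, since 5 of the 10 held a mitochondrial match, against 0 of 1000 randomly drawn distal regions. The matches were 129 bp at 100% identity near Abcb11, 383 bp at 97.9% on chromosome 5, 352 bp at 97.4% on chromosome 10, 365 bp at 99.7% on chromosome 12 and 310 bp at 95.5% on chromosome 6. Sequence present at other places of the genome was found for 3 of the 10, against 8 of 1000 random regions, a count between the outcomes set in advance for and against it, which leaves it undecided for the set. The strongest region, near Pak3, had neither kind of match, and what raised it stays open.

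Summits with a pooled −log10 p under 3 passed the reproducibility threshold in 1746 of 79441 cases (2.20%). A weak summit paired with a stronger summit of the same interval in the other call set is a candidate explanation that stays open. The median of the higher replicate value was 8.48 times the median pooled value of 2.53, but selection for a low pooled value favours such a ratio, which was 2.37 among 3341 weak summits below the threshold, and so does a threshold set on the replicates. Of the 1746 summits, 99.3% lay in an interval with another summit, against 93.3% of all summits of the list. The 13 that lay alone had a median higher value of 38.9.

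The excess of distal regions around pallial and subpallial factors might be a trait of developmental transcription factor genes of any brain region. Pallial and subpallial factors, 50 genes, had a mean log2 ratio of 0.67 (SD 0.96 over genes), against -0.03 (SD 0.90) for 24 midbrain and hindbrain genes, and diencephalic factors, which are of the forebrain but not part of this comparison, had -0.13. The difference of 0.71 (two-sided permutation p = 0.00341) argues against an equal excess in both groups in this list, and it passed in 7 of 9 other settings, but not without replicate 2 (0.54, permutation p = 0.0503) or at the stricter IDR (0.53, permutation p = 0.0538). The 50 genes include some that do not encode transcription factors, such as Slc32a1 (2.22) and Wnt7b (1.88). The comparison therefore covers the lists as written and cannot isolate transcription factor genes. A smaller excess in other brain regions stays open, since midbrain and hindbrain genes lay above matched genes in the other thresholded series list (0.15) and in the replicated list (0.24), and diencephalic factors in the latter (0.24). No explanation tied to the tissue sampled was tested.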

How the results depend on the processing

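The alternatives chosen after the data were examined were the other replicate's pseudoreplicated list, the conservative list for the promoter share, the strongest summit per region and the settings for the difference between pallial or subpallial and midbrain or hindbrain factors, of which 7 of 9 kept the call. The cause of the differences below was not tested unless stated. Leaving out a replicate gave no value for sharing, rank agreement or the promoter against distal odds ratio, which need both. The odds ratio of 7.32 passed in all 6 alternatives (4.67 to 8.98).

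Mean replicate overlap of accessible regions, 76.7%, was 79.6% at the stricter IDR, 73.0% for pseudoreplicated lists, 76.1% with equal numbers of regions, 73.9% with 50% reciprocal overlap, 66.6% for summits within 150 bp, 81.5% for unmerged peaks and 95.6% against the other replicate's pseudoreplicated list. The replicate rank agreement of peak fold enrichment, a Spearman's rho of 0.871, became 0.888 at the stricter IDR, 0.778 for pseudoreplicated lists, 0.852 with equal numbers, 0.884 on −log10 p and 0.710 on mean values per region. The promoter share of accessible regions, 51.9%, was 49.0% within 250 bp and 55.7% within 2500 bp, 59.6% for unmerged peaks, 49.4% in the conservative list, 40.9% in the other thresholded series list, 27.7% in the replicated list and 62.4% at the stricter IDR. On leaving out each replicate it was 50.1% to 53.7%.

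For gene list promoter accessibility, the 7 lists above expectation became 4 at the stricter IDR, 4 with 1 start per gene and 3 when matched on CpG ratio, and the 8 below became 5 when matched. Within 250 bp the pallial (75%) and subpallial (76.9%) calls ended. Leaving out each replicate gave 8 to 13 lists below, the 13 being without replicate 2, where choroid plexus (22.2%), oligodendrocyte (25%), pericyte (31.8%), diencephalic (29.2%) and midbrain and hindbrain genes (25%) gained a call. The endothelial call ended at 40% in the other thresholded series list and 55% in the replicated list, where Hox genes, still below, stood at 35.9%. Over lists and numbers of lists called, 163 of 216 values stayed the same. A list did so by keeping direction and side of the threshold, and a number of lists by staying near its main value. The call was lost for 22 values and gained for 13. Direction turned for lists that had not passed. In the replicated list this held for diencephalic (79.2%), choroid plexus (83.3%), midbrain and hindbrain (79.2%), astrocyte (81.2%) and pericyte genes (77.3%), and in the other thresholded series list for astrocyte genes (62.5%). Cajal-Retzius genes, at 50% to 75% on leaving out each replicate, turned at 50% without replicate 2, at the stricter IDR and with 1 start per gene, and at 56.2% within 250 bp. Matched on CpG ratio, where only the expectation moves, Cajal-Retzius (62.5%) and astrocyte genes (50%) turned, and so did the liver list (27.3%), which had passed.

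For distal regions, the 7 lists above expectation became 4 to 7 on leaving out each replicate, with 4 without replicate 2. The 2 below became 1 in the other thresholded series list, the replicated list, at the stricter IDR and over 5 kb, and also 1 on leaving out either replicate. Of 216 values, counted in the same way, 170 stayed the same, 16 lost the call and 6 gained one. The gains were Cajal-Retzius and midbrain and hindbrain genes in the other thresholded series list (0.31, 0.15) and the replicated list (0.42, 0.24), diencephalic genes in the latter (0.24) and housekeeping genes at the stricter IDR (0.17). The oligodendrocyte list, which had passed, turned to -0.21 over 5 kb. Among lists that had not, turns against the random mean were, at the stricter IDR, Cajal-Retzius (-0.41), microglia (-0.16), endothelial (-0.25) and liver genes (-0.27). In the replicated list they were pericyte (-0.33), liver (-0.47) and muscle genes (-0.24), and within 100 kb diencephalic (-0.40) and liver genes (-0.36). Over 5 kb they were liver (-0.26) and housekeeping genes (-0.12), without replicate 2 erythroid (-0.037, against -0.20 without replicate 1) and liver genes (-0.26, against -0.20), and liver genes also in the other thresholded series list (-0.32), with a pseudocount of 2 (-0.062) and without unsequenced bases (-0.22). Liver genes lay at the random mean to begin with, at -0.21. The ratios of the 20 top genes stayed above 0 in 180 of 180 values, lowest 0.66, but 96 moved by more than the replicate SD.

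For consensus sequences and numbers of sequences called, counted in the same way, 419 of 499 values stayed the same, 32 lost the call and 17 gained one. GC matching, which also left fewer summits, took distal enrichments from 14 to 8, promoter enrichments from 9 to 2 and promoter depletions from 10 to 1. Of the lost enrichments, folds fell at promoters for NRF1 (3.48 to 1.00), CRE (3.01 to 1.42), SP/KLF (1.83 to 1.10), CACGTG (1.69 to 1.03), the partial REST sequence (1.85 to 1.5) and CAGCTG (1.27 to 1.13), and at distal summits for NFI (3.22 to 2), SP/KLF (1.94 to 1.29), CACGTG (1.54 to 1.23) and TEAD (1.11 to 1.01), but rose for distal CRE (2.25 to 2.62) and promoter RFX (1.27 to 1.35). It turned distal NRF1 (0), ETS (0.381), MEF2 (1.5) and FOX (1.22), and promoter CAGATG (1.00), SOX (1.36), TAATTA (1.22), AP-1 (1.40) and FOX (1.29), none of which passed afterwards. The other turns were in sequences that had not passed. Distal T-box went to 0.774 with the strongest summit, 0.963 and 0.958 in windows of 50 and 100 bp, 0.927 with flanks 1000 bp away and 0.909 to 0.962 without each replicate. Distal MEF2 went to 1.08 with the strongest summit, 1.07 in 50 bp windows and 1.06 with farther flanks, and distal FOX to 1.00 in the other thresholded series list and in 100 bp windows. Promoter SOX went to 1.01 in the replicated list, 0.944 to 1.02 on leaving out each replicate (1.02 without replicate 1) and 1.02 in 50 bp windows, the POU octamer to 0.990 in the replicated list, 0.994 to 1.06 on leaving out each replicate (0.994 without replicate 1) and 0.845 with farther flanks, MEIS to 0.958 with farther flanks and the NFI palindrome to 0.75 in 50 bp windows. Unknown depth leaves open how far the shorter list of replicate 1 reflects its sequencing.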

Other observations

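Accessible regions were unevenly spread over the chromosomes. In the conservative list, chromosome 11 had the highest density, 14.9 regions per Mb of sequenced bases, followed by chromosome 19 with 13.4, and chromosome 14 had the lowest density of any autosome, 9.38. The X chromosome had 804 regions, or 4.79 per Mb, with 3.80 in replicate 1 and 4.49 in replicate 2, lower than every autosome in both replicates. Chromosome Y had 14 regions, or 0.153 per Mb. No test was made of these densities.

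Many regions missing from the other replicate's thresholded list were in its longer list. This held for 3035 of 4120 such regions of replicate 1 (73.7%) and for 6966 of 8141 of replicate 2 (85.6%). Against the other replicate's pseudoreplicated peaks, a comparison chosen after the data were examined, 95.4% of replicate 1 regions and 95.8% of replicate 2 regions, over all regions, found a partner. The 11782 genes with a promoter region in both replicates compared with 1076 that had one in a single replicate.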
